A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

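The series holds 6 two-colour tiling arrays of Schizosaccharomyces pombe, 3 of cdc25-22 (WT) and 3 of cdc25-22 rad3Δ, each with the IP of the RPA subunit Ssb1 in one dye and its input in the other, per the labels. The IP was in the green dye on replicates 1 and 2 and in the red dye on replicate 3 of both strains. Samples were grouped by strain from their titles, and replicate numbers come from the same titles. The labels' extraction and labelling protocols speak of RNA, although the channels are labelled IP and input, and the input of rad3Δ replicate 3 is labelled cdc25-23 where its IP is labelled cdc25-22. Neither wording was resolved, and the groups did not depend on them.

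The deposited scanner files hold spot intensities made with Agilent Feature Extraction, version 10.7.3.1 per the submitters' processing notes and versions 10.7.1.1 and 10.7.3.1 per the file headers. Per the file headers, the processed intensity of each dye was background-subtracted, spatially detrended and scaled by 1 linear dye factor per array, and the lowess factor was 0, so no intensity-dependent step was applied. Median pixel intensities of spots and of their local background were deposited too. The deposited LogRatio column is a log10 ratio of red over green processed signals. The authors' series matrix holds a linear ratio of IP over input with no further centring: set against the scanner ratios its columns correlated at 1, and 100% of values were equal within 0.01. Its column medians were 1.01, 1.03 and 1.06 for WT and 0.996, 1.02 and 1.02 for rad3Δ, and it left out the mitochondrial probes. It was used as an alternative.

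The probe coordinates are those of a build that the file headers call Spombe:NCBI:Feb2002. To find where they match the reference assembly ASM294v3, the length of 100 neighbouring probes at a time, which is shorter where G+C is high, was correlated with the G+C content of the reference at a series of offsets. No array signal entered this check. On chromosomes II and III and on chromosome I below position 3722495, 359 of 364 windows had their best offset within 12 bp of 0, with a median correlation of -0.56 at offset 0. In the 62 windows of the rest of chromosome I the median best offset was 6150 bp, with a correlation of -0.03 at offset 0 and -0.62 at the best offset. Genes and AT-rich islands were therefore named only in the matching part, which holds 36483 probes or 85.6%. Positions on the rest of chromosome I are given in the files' own coordinates, were not converted and carry no gene names. Each centromere was taken as the middle of the 50 kb window with the fewest probes.

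Arrays were described first by signal. Median processed input intensity was 969 to 1106 and median IP intensity 1007 to 1145, spots saturated in either dye numbered 1 to 8 per array, and 2 to 401 spots per array carried an outlier flag and were left out. Control spots were left out, each probe had 1 spot, and log2 of IP over input was centred on the median of each array, with no loess or quantile step, these being ChIP arrays. The SD of this ratio over probes was 0.43 to 0.62. All 6 arrays entered one linear model with a mean per strain and a term for dye orientation, coded so that the strain value is the midpoint of both orientations; means ± SD in the text are plain means of 3 arrays. The model was fitted with limma 3.58.1 in R 4.3.3, with two-sided tests and Benjamini-Hochberg adjustment at 0.05. Its statistics were moderated, with prior degrees of freedom of 9.02 for probes and 31.7 for regions called on the average. Residual degrees of freedom were 3. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. In 45 probes the input was not well above background on any array of a strain, so that their ratio there is only a bound; 1 of them is among the probes that differed. Genes holding such a probe were left out of the named rises and falls.

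Regions were runs of at least 3 neighbouring enriched probes no more than 1000 bp apart. They were called in each strain and, for the comparison of strains, on the average of both, so that the choice favoured neither strain. Runs of probes that differed between strains used the same rule and were added after the data had been seen. Loci were protein-coding genes with at least 2 probes whose middle lay in the gene, 4152 of them, and 118 tRNA genes taken with 500 bp on either side of their middle. The fixed list of Tf2 retrotransposons held no locus with 2 probes and was not tested. AT-rich islands were stretches of 500 bp windows, moved in steps of 50 bp, with at least 75% A+T, merged where they touched. They gave 360 islands of median width 700 bp. Their placement was tested against 1000 circular shifts along the matching part, one-sided, and in the alternatives against 200, two-sided. Gene lists were tested with camera of limma at a preset correlation of 0.01 and again at an estimated one, and with fry. Values of single loci or domains were compared with an exact permutation test over arrays, two-sided, whose smallest p for 3 against 3 is 0.1. Input was compared as the median-centred log2 input signal, within slides and in limma with the dye term, since arrays of opposite dye are not comparable directly.

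Genes and regions were named by a rule written before the data were examined. It took, of the regions called on the average, the 10 with the highest mean in each strain that were positive in every array of it, up to 10 with the largest rise and up to 10 with the largest fall past the test without overlap between the arrays of the strains, and the same for rises and falls of genes. rad3, ssb1, ssb2, ssb3, ura4, hus5, the ars3002 region, the ribosomal DNA, cdc22, suc22, cdc18, mik1, hht2 and hhf2 were always to be named if measured. Regions carry the genes they overlap or, between genes, both neighbours. Runs and members of lists are named beyond that rule, after their values were seen.

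The replicate number, the slide and the scan group the arrays in the same way, and each of the 3 slides holds 1 array of each strain, that of WT always at position 2 and that of rad3Δ always at position 4 per the file headers. Position on the slide is thus confounded with strain, and values within slides do not address it. Arrays with the same number deviated together from their strain means, with correlations of 0.399, 0.361 and 0.482 over probes, and at most -0.105 with any other number. The numbers were therefore taken to pair the samples through the shared slide. The fit without a block had been fixed before the data were examined and was kept, and the fit with replicate number as a block in place of the dye term is given where it changes a call or a count by over 1.5 times, and values within each slide are given as ranges.

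Alternatives fixed before the data were examined were: no dye term, the replicate block, centring on the mode, no centring, normexp background correction with offset 50, loess, the authors' matrix, only the 40412 probes well above background everywhere, 1 kb bins, an intensity trend, each array left out, runs of at least 5 probes, an adjusted p of 0.01, islands of 72% or 78% A+T, other island flanks, gene flanks of 500 bp, at least 4 probes per gene, an estimated correlation for lists, smaller domains and unprocessed input signal. Where mean pixel signals were planned, median pixel signals were used, since those are the unprocessed columns of these files. The slide as a block is the same fit as the replicate block and was run once. Regions and loci were not recomputed on 1 kb bins. A lowess correction for G+C content (span 0.2), alone and with the block, and the matching part on its own were added after the data had been seen.

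The fits were tested on simulated data, with known changes added to the fitted mean and dye effect of each probe and normal noise whose spread was drawn from the distribution limma fitted to the real arrays. Noise was independent between neighbouring probes, which the real arrays need not be. The simulation was redesigned after its first output, and its larger case, with more probes changed and by larger amounts, was added because the first recovered few probes. Recovery differed strongly between the cases, and which of the 2 made the difference was not tested. With 445 of 42641 probes changed, 0% of single probes changed by log2 0.5 and 5% of those changed by 1 were called, 4.08% of probes in runs of log2 1 were called, 0 of 49 runs were found by limma, and 2 of 17 calls were false. With 1645 probes changed, 73% of single probes at log2 1, 100% at 2 and 90.8% of those in runs at 1.2 were called, 246 of 289 runs were found, and 72 of 1557 calls (4.62%) were false. Over 4270 loci with 200 changed, 67% of those changed by 0.5 and 98% of those changed by 1 were called, with 3 false among 168 calls. Of 9 lists the 1 shifted by 0.3 was called and 0 others were. Noise was also independent between genes and between arrays. On the real arrays the core histone list had an estimated correlation of 0.26, and arrays of one slide deviated together. The simulation therefore does not show how often lists are falsely called on the real arrays.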

Results

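The positions of replication protein A (RPA), the complex that coats single-stranded DNA, were mapped along the fission yeast genome by chromatin immunoprecipitation of its subunit Ssb1 on Agilent tiling arrays. The strains were cdc25-22, called WT here as in the labels, and cdc25-22 without rad3, the gene of the ATR-family checkpoint kinase, called rad3Δ. The cdc25-22 allele stops cells before mitosis at the restrictive temperature and lets them re-enter the cycle together. Per the labels, cells were held for 4 h at 36.5 °C, released at 25 °C and given 6 mM hydroxyurea, which inhibits ribonucleotide reductase. The time of harvest is not given in the sources used here. Each of the 6 arrays, 3 per strain, set the immunoprecipitated DNA (IP) of 1 sample against its own input in the other dye.

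A total of 42641 nuclear probes were measured on every array, with a median distance of 265 bp between neighbouring starts. Input was well above background at 99.07% to 99.94% of probes and IP at 95.3% to 99.4%, and the number of arrays limits the precision. Values below are log2 IP over input, centred so that the median probe of an array is 0, as mean ± SD of 3 arrays per strain. Dye scaling and centring remove any change in RPA shared by the whole genome. Every rise, fall or level below is therefore relative to the median probe and not an absolute amount of RPA. The ratio correlated across probes at 0.531 to 0.620 between WT arrays and at 0.580 to 0.671 between rad3Δ arrays. It correlated at 0.520 to 0.615 between arrays of different strains that shared a slide. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Every WT array was at position 2 of its slide and every rad3Δ array at position 4, so strain and position cannot be told apart in any comparison below.

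The rad3 gene (chromosome II, 904184 to 913629) was examined first, as a check of the strain labels. Of its 33 probes, 24 between 904607 and 911114 lost their signal in rad3Δ. Their median log2 input signal, relative to the array median, was -0.35 ± 0.15 in WT and -6.02 ± 1.22 in rad3Δ, and their IP signal was -0.51 ± 0.13 and -5.28 ± 0.35 (n = 3 per strain). On rad3Δ replicate 1, 2 of the 24 were well above background in input and 4 in IP, and fewer on the other rad3Δ replicates. The rad3Δ levels are therefore only bounds. These probes were picked by their loss of signal, so no test is given. The other 9 probes of rad3 lay outside the deleted part, with an input of -0.26 ± 0.21 in WT and -0.18 ± 0.18 in rad3Δ. All 6 arrays thus matched their strain labels.

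The first question was where RPA lay in each strain. The strongest regions of WT were near centromeres and were also among the strongest of rad3Δ: the stretch between meu27 and ppc1 on chromosome III (1097235 to 1098896), which holds 1 tRNA gene, stood at 2.11 ± 0.08 in WT and 1.99 ± 0.34 in rad3Δ. The stretch between rpb1, the largest subunit gene of RNA polymerase II, and yox1 on chromosome II (1620842 to 1627570) stood at 1.93 ± 0.12 and 1.92 ± 0.23. Neither passed the test for a difference between the strains (limma adjusted p = 0.546 and 0.952). Across the alternatives the differences ranged from -0.60 to -0.03 and from -0.50 to 0.07, none of them called. Beyond these, the lists of top regions parted, though those of both strains held regions over genes. In WT they held bodies of genes: eng1 (chromosome I, 1000201 to 1001320), which encodes the glucanase that splits the septum, at 1.26 ± 0.57; thi9 (I, 1481188 to 1483049), a thiamine transporter gene, at 1.09 ± 0.36; exg1, pmc4 and pci2 (II, 3514243 to 3518539) at 1.1 ± 0.45; SPCPB1C11.02, SPCPB1C11.03 and xan1 (III, 2074444 to 2081138) at 1.53 ± 0.40; SPBPB7E8.01 (II, 3494920 to 3497630) at 1.18 ± 0.41; and knh4 with apc10 (II, 1972579 to 1973454) at 1.02 ± 0.15. A region on the right arm of chromosome I (5236338 to 5240365), in the part not annotated here, stood at 1.69 ± 0.53 in WT.

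In rad3Δ the top regions were ipp1 (I, 2139904 to 2140550), the inorganic pyrophosphatase gene, at 1.99 ± 0.24, and the space between ddr48 and jmj1 (I, 2524709 to 2525664) at 1.77 ± 0.48. They also held arv1 (I, 1893706 to 1895175) at 1.63 ± 0.25, the space between zuo1 and the telomere protein gene rap1 (II, 3097248 to 3098261) at 1.63 ± 0.35, the space between the replication kinase gene hsk1 and the condensin gene cnd1 (II, 3199405 to 3200087) at 1.62 ± 0.31, and arg82 (I, 2041821 to 2042660) at 1.60 ± 0.28. Runs of at least 3 enriched neighbouring probes formed 412 regions in WT, covering 399.9 kb with a median width of 785.5 bp, and 668 in rad3Δ, covering 1008 kb with a median width of 967.5 bp. Over regions called on the average of both strains, log2 input relative to the array median was -0.35 ± 0.13 in WT and -0.31 ± 0.13 in rad3Δ. The ratio there was 0.44 ± 0.04 and 0.63 ± 0.12. Low input raises the ratio, so region calls do not by themselves show a raised IP signal. No control IP without Ssb1 is among the arrays, so RPA occupancy was not shown apart from the ratio. Of the WT regions, 183 overlapped a rad3Δ region, while 490 rad3Δ regions overlapped none of WT. Single probes enriched over the array median numbered 5452 in WT and 7340 in rad3Δ by limma, with 2979 enriched in both. Probes below the median by the same test numbered 6828 in WT and 7514 in rad3Δ. The counts within a strain changed with the arrays used. Without replicate 3 of WT, where the dye term rests on the lone red array of rad3Δ, 5 WT regions were called, and without replicate 3 of rad3Δ, where it rests on that of WT, 13 rad3Δ regions. Enriched probes numbered 128 and 333 in the same cases. Without replicate 3 of both strains regions numbered 39 and 289, and WT regions numbered 252, 194 and 210 without WT replicate 1, WT replicate 2 and rad3Δ replicate 3. With the replicate number as a block, 694 WT regions were called.

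The second question was which places carried more or less RPA without Rad3, relative to the median probe. Without Rad3 more regions rose than fell, and the 10 largest rises without overlap between the arrays of the strains were 3.19-fold to 4.24-fold. The space between ddr48 and jmj1 rose from -0.31 ± 0.19 to 1.77 ± 0.48, a log2 difference of 2.08 ± 0.16 (SE), or 4.24-fold (limma adjusted p = 2.78e-12). csk1 and pis1 (I, 649560 to 650981), the latter encoding phosphatidylinositol synthase, rose 3.58-fold, glm1 (I, 2398019 to 2399145) 3.35-fold, SPAC18B11.11 (I, 294326 to 295483) 3.34-fold and ipp1 3.31-fold. The space between hsk1 and cnd1 rose from -0.06 ± 0.04 to 1.62 ± 0.31, or 3.20-fold, and nab3 with spo20 (I, 606803 to 609598) rose 3.19-fold. Among the top regions of rad3Δ, arv1 rose 2.95-fold, the space between zuo1 and rap1 2.69-fold and arg82 2.39-fold. Regions on the right arm of chromosome I, not annotated here, rose 3.41-fold at 5538200 to 5538724, 3.34-fold at 5315137 to 5316248 and 3.27-fold at 4358802 to 4359984. Every one of these regions had a limma adjusted p of 3.06e-09 or less except arg82 (6.17e-09), and no WT array reached any rad3Δ array. The p-values of regions rest on a spread pooled over regions, with 31.7 prior against 3 residual degrees of freedom. Their size thus reflects the pooling as well as the arrays. An exact permutation test of 3 against 3 arrays can give no less than 0.1.

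**Figure D1:**
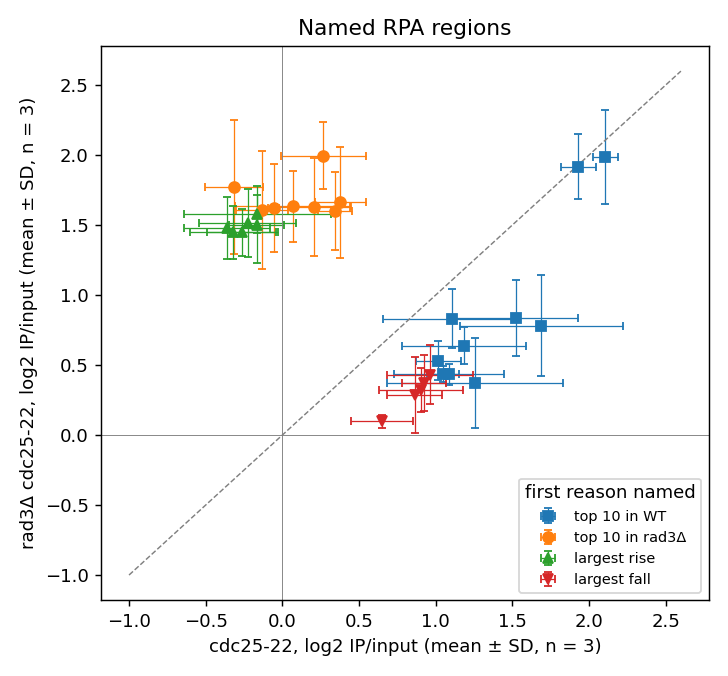
Mean log2 IP over input of the named regions in WT and rad3Δ arrays, as points with mean ± SD of 3 arrays per strain. The space between ddr48 and jmj1 moves from -0.31 to 1.77, while the centromeric stretch between rpb1 and yox1 stays at 1.93 and 1.92.

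**Figure D2:**
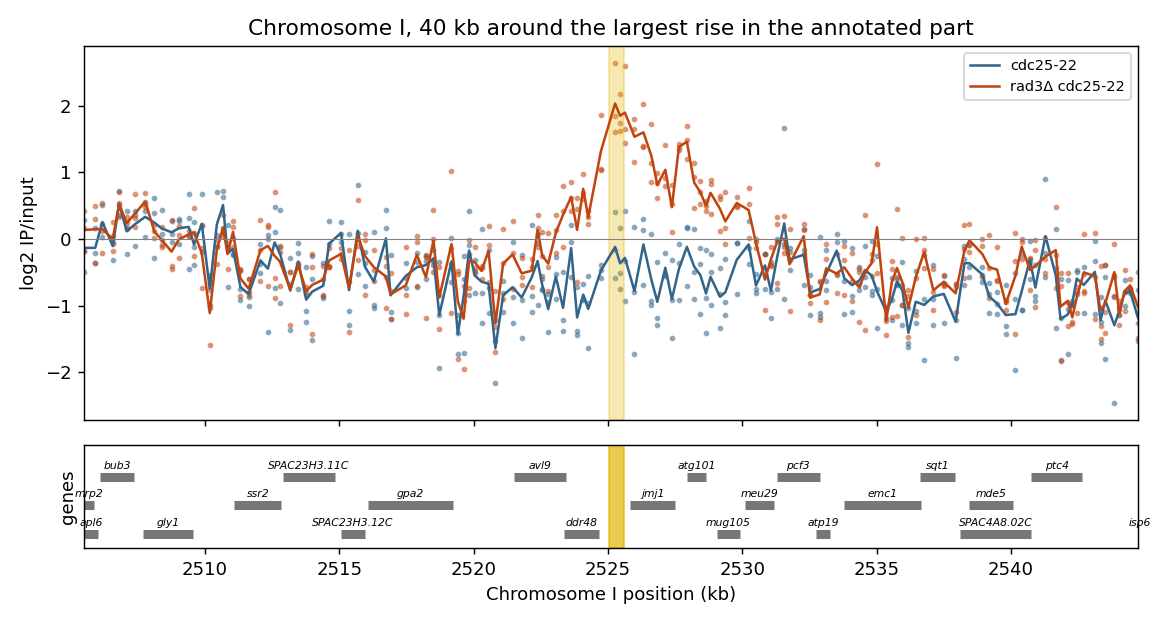
Log2 IP over input along 40 kb of chromosome I around ddr48 and jmj1, with points for single arrays, lines for strain means, annotated genes underneath and the AT-rich island shaded. The rad3Δ line stands above the WT line over ddr48, jmj1, atg101 and mug105, the run from 2523827 to 2529824.

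The largest falls of annotated regions were smaller than the largest rises. They lay over genes, as several of the largest rises also did. The chromosome III region over SPCPB1C11.02, SPCPB1C11.03 and xan1, the last a xanthine dioxygenase gene, fell by 0.69 on the log2 scale (limma adjusted p = 0.000591). The region over thi9 fell by 0.65 to 0.44 ± 0.07, and those over SPBPB10D8.01 and SPBPB10D8.02C (II, 83100 to 83714), mak3 and adg3 (III, 1947592 to 1949238) and SPCC794.03 and SPCC794.04C (III, 246678 to 248501) fell by 0.58, 0.58 and 0.55. SPBPB7E8.01 fell by 0.55, the region over slp1 and eng1 (I, 997255 to 999131) by 0.53 and knh4 with apc10 by 0.49. The region within eng1 fell by 0.89 (limma adjusted p = 0.000201), though its arrays overlapped between the strains. exg1, pmc4 and pci2 did not pass the test at -0.27 (adjusted p = 0.207). In the part of chromosome I without annotation here, 5236338 to 5240365 fell by 0.91, 4072349 to 4072988 by 0.61 and 5022453 to 5023054 by 0.55. Without rad3Δ replicate 1 the calls at SPCPB1C11.02 to xan1 (-0.56), SPBPB10D8.01 (-0.49), SPBPB7E8.01 (-0.47), slp1 with eng1 (-0.41), knh4 with apc10 (-0.42) and within eng1 (-0.73) were lost. Without WT replicate 2 those at SPBPB7E8.01 (-0.31) and slp1 with eng1 (-0.37) were lost (the first also with centring on the mode, at -0.55), and without WT replicate 1 exg1, pmc4 and pci2 passed (-0.52).

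Of 1069 regions called on the average of both strains, limma called 311 higher and 38 lower in rad3Δ. With replicate number as a block, 347 of the same regions were higher and 73 lower. The arrays of the strains did not overlap in 432 regions, or 40.4%, where chance gives 10% for exchangeable and unpaired arrays; arrays here share slides and neighbouring regions are not independent, so that share is only a guide. Over single probes, 1503 were higher and 36 lower by limma, and 2424 and 192 with the block, which held all 1503 and all 36. Without WT replicate 1, 74 probes were lower. Of the 1503 probes, 577 were below the array median by the test in WT, 51 were enriched there and 1236 were enriched in rad3Δ. Without replicate 3 of WT, of rad3Δ or of both, limma called 0 probes at an adjusted p of 0.05, with 2660, 2650 and 2648 higher and 709, 708 and 706 lower at an unadjusted p under 0.05. Regions called and compared anew numbered 168 higher and 13 lower without WT replicate 3, 72 and 1 without rad3Δ replicate 3, and 148 and 3 without both, and 6 and 25 fell without rad3Δ replicates 1 and 2. The normexp background correction also gave 0 probes and 0 regions by limma, with 2510 probes higher and 1182 lower unadjusted and 56 regions of 272 higher and 15 lower unadjusted, and with it none of the named regions passed, with ddr48 to jmj1 at 1.92, csk1 with pis1 at 1.55 and hsk1 to cnd1 at 1.46.

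Neighbouring probes higher in rad3Δ formed 143 runs, which rest on the probe calls of all 6 arrays. The runs covered 267.4 kb, with a median width of 1262 bp. Their mean moved from -0.28 ± 0.14 to 0.94 ± 0.17, a difference of 1.23 that lay between 1.03 and 1.58 on the 3 slides (n = 3 per strain). The runs were picked by this difference on the same arrays, so it is not tested again. Chromosome I held 89 runs, chromosome II 51 and chromosome III 3, for 941, 529 and 33 single probes. The widest run covered 11.53 kb near the right end of chromosome I (5536035 to 5547564), from -0.79 ± 0.27 to 0.82 ± 0.10. Other runs lay over rsm25 and ppr7 (II, 4291271 to 4294869), which rose by 1.75, over SPACUNK4.15, mdb1 and SPACUNK4.13C (I, 2881638 to 2885224) by 1.68, between tlh1 and SPAC212.08C (I, 5867 to 7114) by 1.64, over pdi1 and SPAC18B11.11 by 1.58, over erv25 (I, 1603722 to 1604562) by 1.57 and over SPBC1921.04C and ape2 (II, 2410248 to 2413458) by 1.55. The one run of probes lower in rad3Δ lay in SPCPB1C11.03 (III, 2077933 to 2078468), from 2.07 in WT to 0.79. With replicate as a block, 202 runs were higher and 7 lower.

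**Figure D3:**
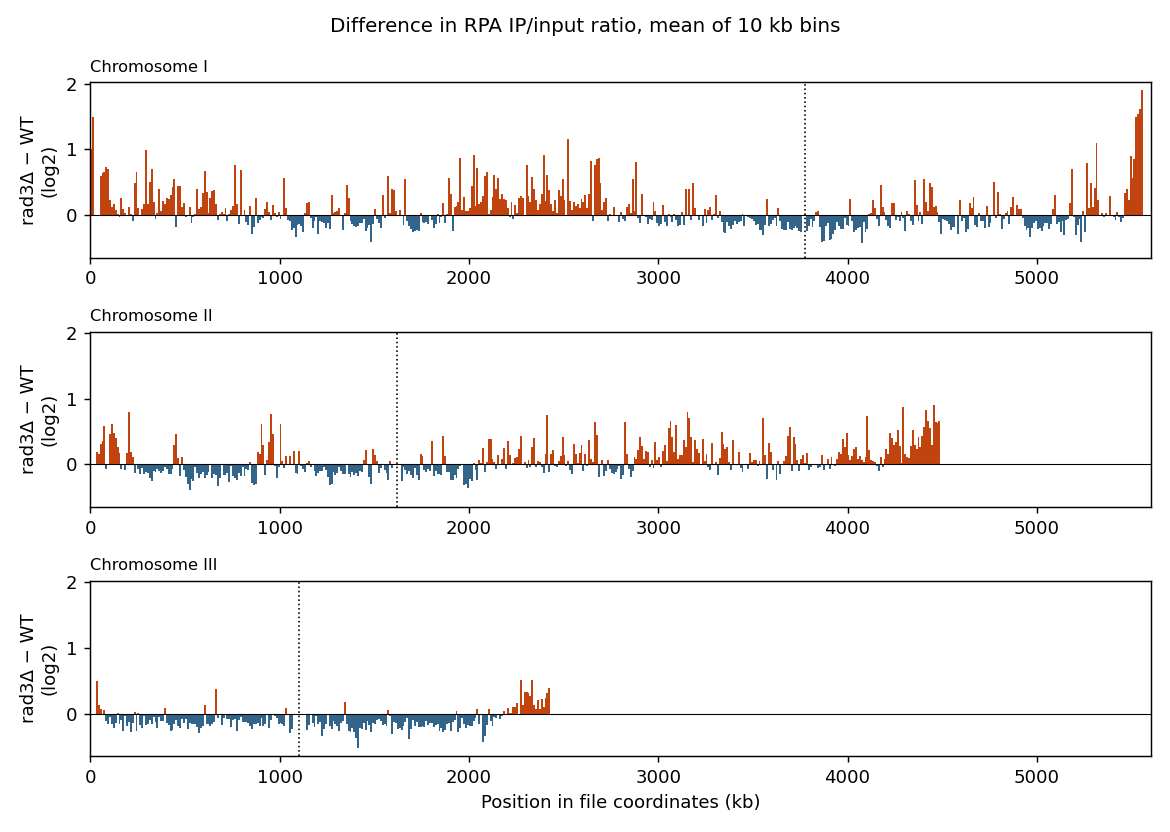
Difference in mean log2 IP over input, rad3Δ minus WT, in 10 kb bins along chromosomes I, II and III, with the centromere as a dotted line. Bins at the ends of chromosomes I and II stand above 0, where the 100 kb ends had a mean difference of 0.66.

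AT-rich stretches between genes are the known sequence mark of replication origins in fission yeast, so RPA was measured at 360 islands of at least 75% A+T, 322 of them with their middle between genes. The islands carried RPA above their surroundings in rad3Δ, while in WT all 3 arrays were slightly below 0. Probes within 1 kb of an island exceeded probes over 5 kb away by -0.05 ± 0.02 in WT and by 0.35 ± 0.11 in rad3Δ. The difference of 0.40 lay between 0.32 and 0.52 on the 3 slides (exact permutation p = 0.1, two-sided, n = 3 per strain). Shifting the islands along the chromosomes 1000 times gave no excess as large as that of rad3Δ (one-sided permutation p = 0.001, the smallest 1000 shifts can give), and for WT p = 0.87. In WT the value of the fit with the dye term was -0.0295, and it turned to 0.0471 and passed without WT replicate 3, where the dye term rests on the rad3Δ arrays alone. It passed below 0 without WT replicate 2 (-0.0551), without replicate 3 of both strains (-0.0488), without the dye term (-0.0461), with the replicate number as a block (-0.0462) and, chosen after seeing the data, with correction for G+C content (-0.0841). The near probes held 33% G+C and the far ones 36.4%.

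Of 323 islands tested one by one with limma, 43 (13.3%) were enriched in WT and 192 (59.4%) in rad3Δ, 42 of them in both. Islands below the array median by the same test numbered 72 in WT and 53 in rad3Δ. In rad3Δ 159 islands (49.2%) rose and 11 fell. The median rise was 0.28. The rise differed between chromosomes. On chromosome I 66 of 107 islands rose, on chromosome II 85 of 157, and on chromosome III 8 of 59 rose and 7 fell. The excess of near over far probes rose by 0.52, 0.40 and 0.12 on chromosomes I, II and III (each exact permutation p = 0.1, two-sided, n = 3 per strain). All 7 annotated regions with the largest rises, among them ddr48 to jmj1, ipp1 and hsk1 to cnd1, lay within 1 kb of an island. Of the annotated runs higher in rad3Δ, 71 of 113 (62.8%) lay within 1 kb of an island, against a mean of 13.9% for shifted islands (one-sided permutation p = 0.001). For the regions of rad3Δ this was 33.8% against 13.1% (p = 0.001 over the same permutation), for those of WT 12.5% against 11.5% (p = 0.31), and for the 28 annotated regions lower in rad3Δ 7.14% against 12.3% (p = 0.86). With the replicate number as a block, 156 islands rose and 11 fell.

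The rise was narrow. From 0 to 1 kb from the islands it was 0.38 (limma adjusted p = 2.58e-18), from 1 to 2 kb 0.25 (2.91e-09), from 2 to 3 kb 0.10 (0.029) and from 3 to 4 kb 0.00 (0.975). Around the summits of regions called on both strains it was 0.19, 0.13 and 0.08 over the same first 3 steps (limma adjusted p = 6.22e-06, 0.00441 and 0.232). The step from 2 to 3 kb from the islands kept its value at 0.10 but lost its call with centring on the mode. The call was also lost without replicate 3 (0.08) and without rad3Δ replicate 1 (0.09). Normexp ended the calls of all 3 island steps, at 0.28, 0.20 and 0.06. Every step of both profiles had the same SE of 0.035, a spread pooled over all steps. These steps share the same arrays and are not independent. The limma p-values of the profiles therefore cannot be read as evidence at the level of replicates. In the first 3 steps of both profiles every rad3Δ array lay above every WT array.

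**Figure D4:**
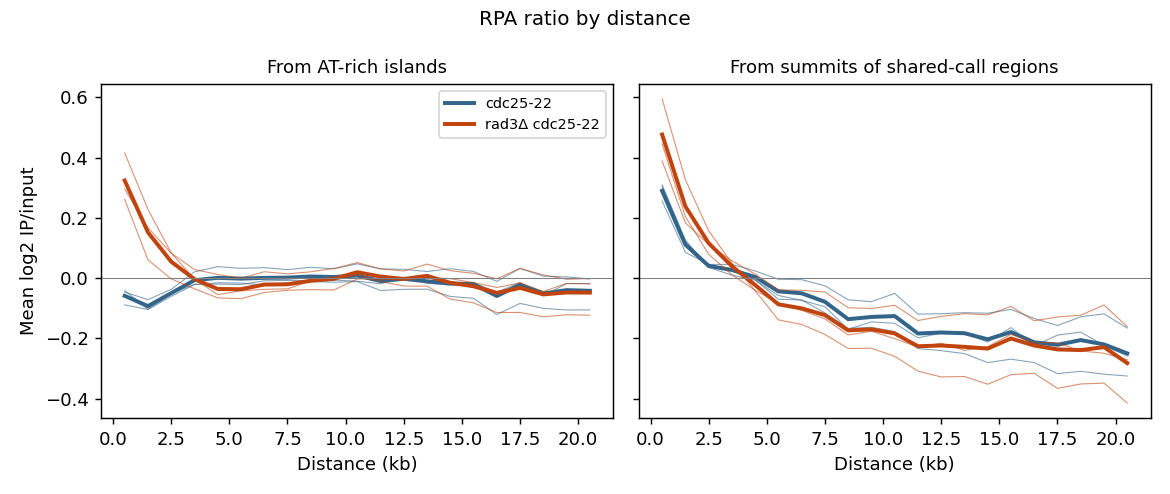
Mean log2 IP over input by distance in kb from AT-rich islands and from summits of regions called on both strains, with thin lines for single arrays and thick lines for strain means. The rad3Δ arrays stand above the WT arrays in the first 2 kb from the islands, by 0.38 and 0.25.

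Loci beside 2 known origins were measured on their own and not compared with the islands. hus5 with 1 kb on either side, next to the origin ars1, stood at 0.04 ± 0.17 in WT and -0.03 ± 0.25 in rad3Δ, with differences of -0.41 to 0.37 on the slides (exact permutation p = 0.6, two-sided, n = 3). ura4 with 5 kb on either side, the neighbourhood of the ars3002 cluster, stood at 0.05 ± 0.07 and -0.13 ± 0.10, with differences of -0.22 to -0.12 on the slides (exact permutation p = 0.1, two-sided, n = 3, the smallest possible).

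The third question was whether whole domains that replicate early or late differed. Relative to the median probe, RPA in rad3Δ was higher over the ends of chromosomes I and II, which replicate late. It was lower over the centromeres, which replicate early. It was higher over the mating-type region, which had also been fixed as an early domain, so the early domains did not move alike. The 100 kb ends of chromosomes I and II moved from -0.33 ± 0.19 to 0.33 ± 0.02 (limma adjusted p = 0.00167), a rise of 0.66 that lay between 0.52 and 0.87 on the 3 slides. The right end of chromosome I rose by 0.93, its left end by 0.78, and the right and left ends of chromosome II by 0.63 and 0.34. The left end of chromosome III, whose probes start beyond the ribosomal DNA, was 0.14 ± 0.07 in WT and 0.12 ± 0.06 in rad3Δ (limma adjusted p = 0.674), and its right end rose by 0.20 (0.0209). The 50 kb on either side of the centromeres fell by 0.15 together (limma adjusted p = 0.00775), and lay between -0.16 and -0.13 on the slides. Centromere III fell by 0.23, centromere I by 0.17 and centromere II by 0.08 (limma adjusted p = 0.00167, 0.00949 and 0.0297). The mating-type region rose by 0.15 (0.0111), and the rest of the arms did not pass the test at 0.02 (0.536). Normexp ended the calls of the ends (0.60), the centromeres (-0.25) and the mating-type region (0.11), and centring on the mode those of the centromeres (-0.15) and the mating-type region (0.15). The exact permutation test (two-sided, n = 3 per strain) gave p = 0.1 for each of these differences except centromere II (0.3), the left end of chromosome III (0.7) and the rest of the arms (0.4). It does not use the pairing by slide. Within slides these 3 differences lay between -0.095 and -0.070, between -0.028 and 0.016 and between 0.009 and 0.030.

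**Figure D5:**
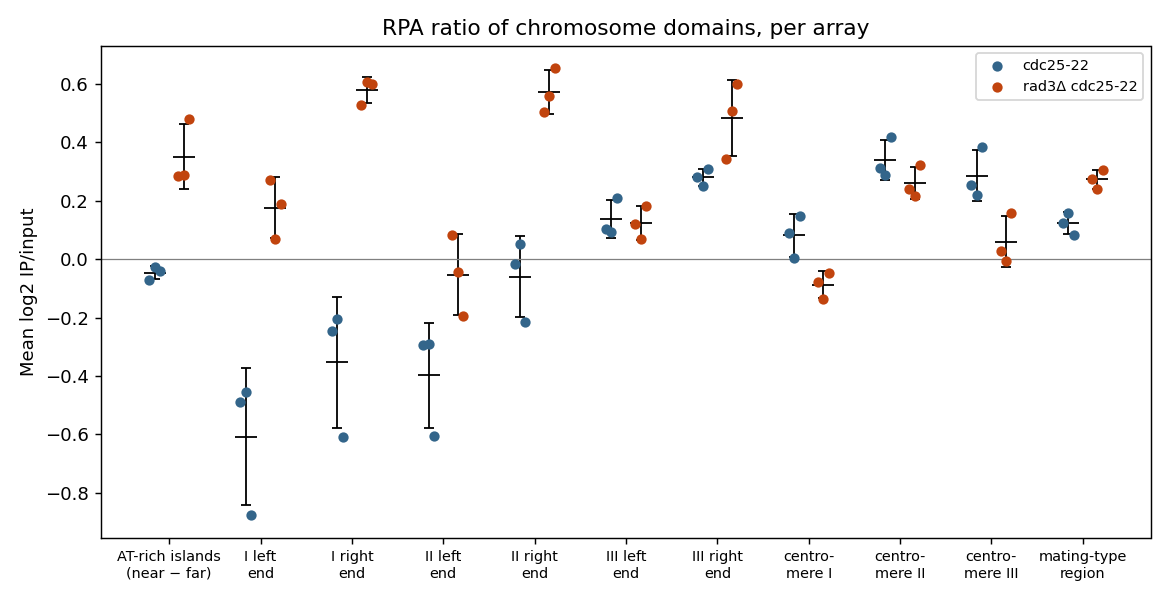
Log2 IP over input per array, with mean ± SD of 3 arrays per strain, for the excess at AT-rich islands, the 6 chromosome ends, the 3 centromeres and the mating-type region. The rad3Δ arrays lie above the WT arrays at both ends of chromosomes I and II and below them at centromeres I and III.

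Over gene bodies, the largest rises were at jmj1, which encodes a JmjC-domain protein (log2 1.74 ± 0.19 SE, 3.35-fold), mdb1, a BRCT-domain protein gene of the DNA damage response (3.12-fold), pis1 (3.1-fold) and glm1 (3.06-fold). They were followed by gmf1 (2.89-fold), the hydroxymethylglutaryl-CoA synthase gene hcs1 (2.84-fold), ipp1 (2.83-fold), cyc2 (2.77-fold), the nucleoporin gene seh1 (2.75-fold) and the respiratory complex assembly gene bcs1 (2.75-fold), each with a limma adjusted p of 0.00118 or less. The largest falls were at SPCPB1C11.03 (-1.05 ± 0.25 SE), xan1 (-0.84), the alcohol dehydrogenase gene adh1 (-0.72) and the neighbouring histone genes hta1 (-0.69) and htb1 (-0.66), followed by the ribosome biogenesis gene rlp7 (-0.59), met26 (-0.59), the translation elongation gene tef3 (-0.53), mug129 (-0.52) and but2 (-0.52), with adjusted p between 0.00631 and 0.0312. Without replicate 3 of either or both strains every one of these falls but that of adh1 lost its call: SPCPB1C11.03 (-0.93), xan1 (-0.77), hta1 (-0.62), htb1 (-0.63), rlp7 (-0.49), met26 (-0.64), tef3 (-0.55), mug129 (-0.56) and but2 (-0.50). SPCPB1C11.03 (-0.87), xan1 (-0.77) and met26 (-0.53) also lost it without rad3Δ replicate 1, and met26 (-0.40) without WT replicate 2. met26 (-0.59) and mug129 (-0.52) lost it without the dye term, and met26 (-0.51) with correction for G+C content, chosen after seeing the data. Of 4270 loci, 411 rose and 56 fell by limma. With replicate number as a block 634 rose, among them all 411, and 273 fell. Of the 411, 171 lay within 1 kb of an island and 38 in the annotated ends of chromosomes I and II, which leave out the right end of chromosome I. suc22, the small subunit gene of ribonucleotide reductase, rose by 0.65 ± 0.16 SE (limma adjusted p = 0.0267). It lost its call without WT replicate 1 (0.59), without rad3Δ replicate 2 (0.61), without replicate 3 of either or both strains (0.46) and with normexp (0.13). The RPA subunit genes ssb1 (0.23) and ssb2 (-0.25), ura4 (-0.11), hus5 (-0.03), mik1 (0.08), cdc18 (0.04), hht2 (-0.24) and hhf2 (0.25) did not pass the test. cdc22, ssb3 and the ribosomal DNA were not analysed here. Without replicate 3 of WT, of rad3Δ or of both, 81 loci rose and 1 fell, and without rad3Δ replicate 1, 31 fell. With normexp limma called 0 of either (422 higher and 224 lower unadjusted), and none of the named genes passed. Rises and falls there were jmj1 1.33, mdb1 1.43, pis1 1.25, SPCPB1C11.03 -1.66, xan1 -1.16, adh1 -0.73, htb1 -0.79 and hta1 -0.18.

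Groups of genes fixed before the data were examined were tested list by list, and the extents of their changes were not compared between lists. The list of chromosome ends holds no gene of the right end of chromosome I, which is not annotated here. Of 62 genes in the annotated ends of chromosomes I and II, 38 rose and 0 fell, and 24 did not pass the test (44 rose adjusted over the list alone). Among them SPAC212.08C rose by 1.45, SPAC212.04C by 1.30, pan5 by 0.98 and gal1 by 0.83. The camera test of limma gave an adjusted p of 7.76e-19 with its preset correlation and an adjusted p = 0.169 with an estimated correlation. Of 552 genes beside AT-rich islands, 164 rose, 5 fell and 383 did not pass the test (205 rose and 16 fell adjusted over the list alone), with camera adjusted p = 5.36e-15 and adjusted p = 0.169 with an estimated correlation. The 5 that fell were adh1, hta1, tef3, the gene lmb1 (-0.51) and the thiamine synthesis gene nmt1 (-0.39). Of 37 genes near centromeres 0 rose or fell, by limma over all loci or adjusted over the list alone, at a median difference of -0.14, with 0 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0248, and adjusted p = 0.169 with an estimated correlation).

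Of the 4 core histone genes measured, hta1 and htb1 fell and hht2 and hhf2 did not pass the test (0 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0248, and adjusted p = 0.308 with an estimated correlation). Of the fixed list of glycolytic and translation factor genes only 6 were measured (fba1, eno101, tdh1, pgk1, tpi1 and adh1), none of them a translation factor; adh1 fell and the other 5 did not pass the test, tdh1 being at -0.43 (0 rose and 2 fell adjusted over the list alone; adjusted p = 0.0248, and adjusted p = 0.308 with an estimated correlation). Of 90 ribosomal protein genes 5 rose, 3 fell and 82 did not pass the test (4 and 2 adjusted over the list alone). rpl3602 rose by 1.32, rpl1801 by 0.88 and rps901 by 0.71, and rps1802 fell by 0.45, with camera adjusted p = 0.0248 in the direction of a fall and adjusted p = 0.376 with an estimated correlation. Of 118 tRNA genes 9 rose, 6 fell and 103 did not pass the test (11 and 13 adjusted over the list alone). SPBTRNAGLU.08 rose by 1.31 and SPATRNALYS.04 by 1.30, while sup9 fell by 0.56 and imt07 by 0.53 (camera adjusted p = 0.0248 towards a fall, and adjusted p = 0.325 with an estimated correlation). Of 11 heat shock and stress genes hsp16 rose by 1.27 and the other 10 did not pass the test (1 rose adjusted over the list alone; adjusted p = 0.293, and adjusted p = 0.376 with an estimated correlation). Of 12 G1/S genes of the MBF transcription factor, rad21 (0.33) and dut1 (0.45) among them, 0 rose or fell by limma, over all loci or adjusted over the list alone, with 2 higher and 0 lower at an unadjusted p under 0.05 (adjusted p = 0.293, and adjusted p = 0.376 with an estimated correlation). With fry, a test of whether the genes of a list move one way on balance, the lists of chromosome ends, centromeres and AT-rich islands passed, each at an adjusted p of 0.0262. Without rad3Δ replicate 2 camera no longer called the histone (mean difference -0.23), glycolytic (-0.19), ribosomal protein (-0.02) and tRNA (-0.02) lists, and without WT replicate 1 neither of the last 2 (-0.03 and -0.02). Normexp ended the calls of the histone (-0.28), glycolytic (-0.23) and ribosomal protein (-0.00039) lists, and correction for G+C content, chosen after seeing the data, those of the glycolytic (-0.20) and ribosomal protein (-0.03) lists.

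The last question was whether the amount of DNA in the input differed, since replicated sequence is present in more copies. Input was slightly higher in rad3Δ where RPA rose. It was higher by 0.19 over the runs higher in rad3Δ, by 0.13 over the ends of chromosomes I and II and by 0.09 within 1 kb of AT-rich islands, on every slide and by far less than the ratio itself (each exact permutation p = 0.1, two-sided, n = 3 per strain). limma gave adjusted p = 0.115, 0.0879 and 0.143, so none passed. With replicate number as a block all of these passed, the islands at an adjusted p of 0.0301. Over centromeres the difference was -0.01 and over the mating-type region 0.03. Across 1225 bins of 10 kb, which are not independent replicates, the strain difference of input and that of the ratio had a Spearman rho of 0.634 and a Pearson r of 0.336. Of single input probes, limma called 0 higher and 7 lower in rad3Δ, with 108 and 65 at an unadjusted p under 0.05, and the only run among the lower ones (II, 909012 to 909534) lay in rad3.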

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

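The tests of explanations in this part were chosen after the results had been seen.

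RPA at AT-rich islands stood out because the excess of near over far probes was below 0 on all 3 WT arrays and above 0 on all 3 rad3Δ arrays, at -0.05 and 0.35, a difference of 0.40; in the shifting test of the report only the sign in rad3Δ passed (one-sided permutation p = 0.001). A bias with G+C content would raise islands of all chromosomes alike, but chromosome III, whose islands hold as much A+T, showed at most 41.7% of the smaller rise of chromosomes I and II on any slide, and 0.33 was left after correction for G+C content. Both strains share slide, scan and dye orientation at each replicate number, so an additive effect of these cancels within a slide by design. The lowest rise within a slide was 0.32, which shows only that the rise did not come from a single slide. Less input DNA at the islands of rad3Δ would raise the ratio, but input there was higher in rad3Δ on every slide, by 0.0549 or more. The values for G+C content and for input argue against those explanations as the whole cause. Position on the slide, 2 for every WT and 4 for every rad3Δ array, cannot be told apart from strain, so an effect of position and a difference between the strains both stay open.

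RPA at the ends of chromosomes I and II stood out in the same way, at -0.33 in WT and 0.33 in rad3Δ, a difference of 0.66, as did the left end of chromosome I alone (-0.61 and 0.18, difference 0.78) and its right end (-0.35 and 0.58, difference 0.93); each sign passed against 0 by limma (adjusted p of 0.00401 or less) except that of rad3Δ at the left end of chromosome I (0.135). Fewer copies of the ends in the input of rad3Δ would raise the ratio, but input there was higher in rad3Δ by at least 0.0685 on every slide. After correction for G+C content at least 84.1% of the rise was left on every slide, over the probes that match the reference, which argues against a G+C bias as the whole cause. The lowest rise within a slide was 0.52, so the rise did not come from a single slide. An additive slide, scan or dye effect cancels within a slide by design and was not tested by this. Longer or rearranged chromosome ends in one strain were not tested, and position on the slide cannot be told apart from strain here either.

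The ratio over centromere I was above 0 on all WT arrays and below 0 on all rad3Δ arrays, at 0.08 and -0.09, a difference of -0.17, and each sign passed against 0 by limma (adjusted p = 0.0188 and 0.0477). That 0 is set by the median: centred on the mode, which lay at -0.11 on rad3Δ replicate 1, this array would be above 0.

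The input channel, apart from the comparisons of RPA, held a signal at ura4: over 9 probes (chromosome III, 115080 to 117114) input moved from 0.72 ± 0.10 in WT to 1.06 ± 0.15 in rad3Δ, a difference of 0.34 or 1.27-fold (exact permutation p = 0.1, two-sided, n = 3 per strain), and by 0.01 in the 10 kb on either side. The stretch was extended from the gene over neighbouring probes for as long as their input was higher in rad3Δ on every slide. Its difference and p-value were thus picked by the same values, and the flanks start where that rule stopped. Genes within 1 percentage point of the G+C content of ura4 had a median input difference of -0.0120, which argues against a G+C bias. The lowest difference of the gene within a slide was 0.28, so it did not come from a single slide. An additive slide, scan or dye effect cancels within a slide by design and was not tested by this. Another copy of a ura4 fragment in the rad3Δ strain, where ura4 is a common marker for gene deletion, is a candidate explanation that was not decided: ura4 ranked 2 of 4152 genes by input difference, but that rank restates the observation. It stays open: IP of the gene was higher by 0.26 and that of the stretch by 0.18 (exact permutation p = 0.1 and 0.2, two-sided, n = 3 per strain), the gene ranked 757 by IP, and its input difference of 0.39 had a limma adjusted p of 0.0566 among all input values and 0.0415 among the 6 compared across alternatives, a call lost without WT replicate 1, 2 or 3 (0.37, 0.40 and 0.39), rad3Δ replicate 3 (0.39) or replicate 3 of both (0.39). Position on the slide cannot be told apart from strain here either.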

How the results depend on the processing

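Correction for G+C content and the part matching the reference were chosen after the results had been seen, and every other alternative before the data were examined.

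Over 33 main results and 600 alternative values, 472 were unchanged, 40 lost a call, 12 gained one, 75 counts moved by over 1.5 times and 1 value reversed. For 58 named regions and genes and 1069 values, 973 were unchanged, 95 lost a call, 1 gained one and 0 reversed. Unchanged means the same call, a count within 1.5 times, or no call in either setting. A change of sign without a call in either setting was counted as unchanged too, as for hus5 (-0.15 to 0.12) and hhf2 (-0.11 to 0.55). The rise of probes near islands over those far from them kept its call in every alternative run, by the shifting test. That test asks where the rise lies and does not use the spread between arrays. The profile by distance and the list of genes beside islands did not keep their calls throughout. Loess, the authors' matrix, the intensity trend, dim probes left out, other island and domain sizes and unprocessed input changed no main call and moved no count by over 1.5 times. The authors' matrix holds the same ratios as the scanner signals, so its agreement was fixed in advance and is no separate check. Unless a reason is given, the cause was not tested. IP was well above background at 95.3% of probes on the lowest array, and 3 arrays per strain limit what smaller differences could be called.

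With 1 kb bins 2953 units were enriched in rad3Δ and 2392 in WT, fewer because fewer units were tested, and 136 were lower in rad3Δ. At an adjusted p of 0.01, a stricter threshold, 385 rad3Δ and 89 WT regions were called and 195 shared regions were higher and 14 lower. With runs of at least 5 probes, a stricter rule, these were 299, 101, 161 and 20. With the correlation estimated, camera no longer called the histone (-0.34), chromosome end (0.47), island (0.27), centromere (-0.10) and glycolytic (-0.28) lists. The same held for the ribosomal protein (-0.0619) and tRNA (-0.0472) lists, all at unchanged means. For the centromere list the estimate was -0.0119, below the preset 0.01. A higher correlation between genes therefore does not account for the loss of that call. G+C correction, with or without the block, was also restricted to the part matching the reference. With it the glycolytic (-0.20) and ribosomal protein (-0.0284) lists lost their calls, 967 probes were higher and the WT islands passed at -0.0841. In the matching part alone, which leaves out the rest of chromosome I, 20 probes were lower. With 500 bp gene flanks 160 loci fell.

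Centring on the mode ended the calls of centromeres (-0.15), the mating-type region (0.15) and the island profile from 2 to 3 kb (0.10), and left 37 loci and 23 probes lower; without centring 111 loci were lower. Without the dye term 260 loci rose and 18 fell, 9 probes and 23 shared regions were lower, 239 WT regions were called, the input at islands (0.0902), ends (0.13) and runs (0.19) passed and WT islands passed at -0.0461. Normexp gave 0 probes (2510 higher and 1182 lower unadjusted), 0 loci (422 and 224 unadjusted) and 0 shared regions (56 and 15 unadjusted) either way by limma, 3370 rad3Δ and 823 WT enriched probes, and 170 rad3Δ and 23 WT regions. It ended the calls of centromeres (-0.25), ends (0.60), the mating-type region (0.11), the histone (-0.28), glycolytic (-0.23) and ribosomal protein (-0.00039) lists and the profile steps (0.28, 0.20 and 0.0648).

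With the replicate block 634 loci rose and 273 fell, 2424 probes were higher and 192 lower, 91 shared regions called anew were lower, 694 WT regions were called, the input at islands (0.0902), ends (0.13) and runs (0.19) passed and WT islands passed at -0.0462; the block changed no other call. With the block and G+C correction together the mating-type region (0.11) and the histone (-0.32), glycolytic (-0.20) and ribosomal protein (-0.0284) lists lost their calls, 624 loci rose and 290 fell, 207 probes were lower and WT islands passed at -0.10.

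Leaving out arrays gave 333 to 8114 enriched probes in rad3Δ and 128 to 5562 in WT, 13 to 749 and 5 to 426 regions, 0 to 1485 probes higher and 0 to 74 lower, 72 to 303 shared regions higher and 1 to 52 lower, and 81 to 399 loci higher and 1 to 68 lower. Probe counts of 0 came without replicate 3 of either or both strains, where limma gave unadjusted counts of 2648 to 2660 higher and 706 to 709 lower, and a lowest adjusted p of 0.0578 to 0.0579. These 3 settings give the same strain differences because the lone array left with IP in red is absorbed by the dye term. Ranges were -0.46 to -0.23 for the histone list, -0.35 to -0.19 for glycolytic, -0.0950 to -0.0216 for ribosomal protein and -0.0758 to -0.0185 for tRNA genes, 0.0847 to 0.13 for the profile from 2 to 3 kb, 0.31 to 0.46 for ura4 input, whose call was lost without WT replicate 1, 2 or 3, rad3Δ replicate 3 and replicate 3 of both, and -0.0551 to 0.0471 for WT islands, which reversed to 0.0471 without WT replicate 3.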

Other observations

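The tests in this part were chosen after the results had been seen, except the splits of the arrays.

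Single islands of chromosome III had a median difference of -0.07, against 0.45 on chromosome I and 0.34 on chromosome II. The excess of near over far probes on chromosome III was nonetheless higher in rad3Δ, by 0.12 (0.11 to 0.15 on the slides), so the median holds any shift of the whole chromosome as well. Shuffling the chromosome among islands 100000 times gave a two-sided permutation p of 2e-05, with islands counted as independent, which neighbours are not. It restates the observation that prompted it and decides nothing on its cause. A version with islands of chromosomes I and II matched for A+T and width (59 islands, median 0.50) was also run and is no separate test.

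Bins of 10 kb with a higher ratio in rad3Δ also held more input DNA there. The Spearman rho was 0.638 over 1043 bins that match the reference and 0.615 after G+C correction; within slides the lowest rho, with or without the correction, was 0.422. The ratio of a slide set against the input of the other slides, which shares no spot, gave 0.474, 0.496 and 0.731. More copying of these bins in rad3Δ cells is a candidate explanation, found on the same data; bins are not independent replicates.

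The 66 mitochondrial probes, outside the nuclear comparisons, stood at -0.93 ± 0.49 in WT and -1.25 ± 0.89 in rad3Δ (exact permutation p = 0.7, two-sided, n = 3 per strain).

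The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1503 higher probes and the highest other split 53; for regions called on the average these were 311 and 0 higher and 38 and 0 lower, for loci 411 and 0 higher and 56 and 0 lower, and for islands 159 and 0 higher, all by limma. For each of these 6 counts 1 split of the 10, the real one, gave as many. Of the 4 splits that part every pair of replicate numbers, the other 3 gave 0 probes by limma.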
